A study of Mus musculus with 16 samples.

How the data were processed

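Total RNA was taken with TRIzol from whole lungs of C57BL/6 mice, and 0.2 ug per sample was labelled with Cy3 by the Agilent low-input QuickAmp method and hybridised to 1-colour arrays, per the labels. LNA-miR-199a-5p or LNA-control was instilled into the trachea at 5 mg/kg 4 and 2 days before bleomycin (1 unit/kg) or PBS and again 4 days after. The day of collection and the sex of the animals are not stated. The 16 arrays fell into 4 groups named in the labels: 3 for PBS with LNA-control, 3 for PBS with LNA-miR-199a-5p, 5 for bleomycin with LNA-control and 5 for bleomycin with LNA-miR-199a-5p. The labels number the replicates within each group and do not say that each is a separate animal, so some of the spread between arrays may be technical.

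The deposited table holds log2 intensities, which the authors prepared with limma (no version given). The deposited log2 values are already quantile normalized: sorted values of all arrays lay within 0.0974 of each other. Background correction, scanner software and filters are not stated. The table has 62976 spots with values from 4.61 to 18.3. Of these, 31465 probes had a gene name in the platform table supplied with the files and 31511 had none, control spots among them, which are not marked. Gene symbols were updated through RefSeq accessions for 29036 matched probes, which changed 2933 symbols, and for the 6086 genes with several probes the probe with the highest mean over all arrays was kept. That left 20863 genes, all of which were tested with no further filter or scaling. Among the genes called with several probes, a probe called in the other direction was present for 7 of 1203 after bleomycin with LNA-control and for 66 of 1687 for the inhibitor in bleomycin lungs. Signal of arrays has no count depth, so the number of arrays sets the precision. The lowest correlation between arrays of a group was 0.985, and no array repeated another (smallest median absolute difference 0.0942).

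One limma model (version 3.58.1, R 4.3.3) of the 4 group means was fitted to all 16 arrays with lmFit and eBayes. There were 5 contrasts: bleomycin against PBS within each LNA, LNA-miR-199a-5p against LNA-control within each treatment, and their interaction. Genes were called at a Benjamini-Hochberg adjusted p under 0.05, adjusted over all genes of a contrast, and all tests were two-sided. A change of sign or size put into simulated unchanged groups was tested with the same code: after a change of 1 on the log2 scale, 97.0% of genes were recovered for bleomycin with LNA-control, 98.5% for bleomycin with LNA-miR-199a-5p and 98.5% for the inhibitor in bleomycin lungs. After a change of 0.5 these were 61.2%, 58.2% and 76.1%. The simulated sets had independent noise and 179 to 189 genes called, where the data had 2786 to 5188 called in these comparisons. Fewer changed genes make the adjusted threshold stricter, so these shares do not give the share missed in the data.

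Before the data were examined, 35 gene lists with 731 members were written down for matrix, fibroblast, leukocyte, epithelial, endothelial, stress and division genes and for blood, heart, fat, thymus and sex-linked genes, of which 703 members were measured. Each list was tested with camera at a preset correlation between genes of 0.01, adjusted over the lists of a contrast, and again with an estimated correlation. The rotation test fry, which asks whether the genes of a list move one way on balance and does not compare them with other genes, was run as an alternative. Counts of called members are given over all genes and adjusted over the list alone. The 6 sex-linked genes served only as a check of the groups, with 5 measured, and their list passed in no contrast under the preset correlation. The list mixes Xist with genes of the Y chromosome, which move in opposite ways with sex, so its test cannot show a difference in sex. Read one by one, Xist was 4.85 to 5.46 and the Y-linked Eif2s3y 11.41 to 12.11 on every array, the pattern of male tissue.

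The genes named in the text follow a rule fixed with the lists. For each contrast it takes the 10 largest rises and the 10 largest falls among called genes with a mean above the median of all genes (8.47) and no overlap between the arrays compared. For each list it takes up to 4 members with the smallest p after bleomycin with LNA-control and up to 2 for the inhibitor in bleomycin lungs. It adds 12 genes of interest in lung fibrosis and miR-199a-5p biology: Cav1, Dnm3os, Dnm1, Col1a1, Col3a1, Fn1, Acta2, Spp1, Timp1, Sftpc, Cdkn1a and Tgfb1. Only part of the genes the rule gives are named.

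Correlations of effects were taken across genes, and their covariance was set against 100 sets of simulated unchanged groups with the same shared arrays. For the effects that share the bleomycin arrays with LNA-control, those arrays were also split 3 and 2 in all ways so that none entered both effects, and the changed genes were chosen again from each part alone. For the bleomycin effects of the arms, the PBS arrays were split so that no replicate number entered both. The residuals of arrays with the same replicate number correlated at 0.411, 0.108 and 0.497 between the PBS groups and at -0.373 to 0.0271 between the bleomycin groups, so counts with the replicate number as a block are given for PBS lungs. Other splits of the arrays were refitted in the same way, all splits or 100 drawn with a fixed seed.

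Alternatives written down beforehand were repeated quantile normalization, centring each array on its 75th percentile, leaving out the dimmest 30% of genes, the mean of a gene's probes, every spot on its own, a trended and robust variance, array weights, a fit of only the groups compared, RNA integrity as a covariate, the replicate block, other thresholds, and each array left out. Lists of squamous epithelium, skeletal muscle, brown fat and pituitary genes were written after the data were seen, and so were the alternatives with tissue lists as covariates, those without the arrays rich in thymus or poor in brown fat transcripts, the block within PBS arrays, the choice of genes from 1 part of the split and the PBS arrays of different replicate numbers. A planned test of genes with miR-199a-5p seed sites was not run, because no transcript sequence was at hand. Spots without a gene name entered only the fit of every spot.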

Results

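Messenger RNA was measured in whole lungs of C57BL/6 mice on 16 arrays of a 1-colour Agilent mouse design. The animals received an oligonucleotide made of locked nucleic acid (LNA), which was directed against the microRNA miR-199a-5p or was a control, and then either bleomycin, a DNA-damaging drug that injures the lung and is used to bring on fibrosis, or its vehicle PBS. Lungs given PBS were represented by 3 arrays with LNA-control and 3 with LNA-miR-199a-5p, and lungs given bleomycin by 5 arrays with each LNA. The title of the series puts the question as the effect of silencing miR-199a-5p on fibrosis brought on by bleomycin. RNA integrity numbers ran from 7 to 10, with group means of 8.33 in both PBS groups, 8.2 with bleomycin and LNA-control and 9 with bleomycin and LNA-miR-199a-5p. Values were log2 intensities, 20863 genes were tested, and changes are given as log2 fold changes ± standard error from limma, with 3 arrays for PBS groups and 5 for bleomycin groups. The number of arrays limits the precision, and the p-values measure the spread between samples as the labels name them.

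The first comparison asked what bleomycin did to lungs given LNA-control. Macrophage genes rose. Spp1, which encodes the matrix protein osteopontin, was higher by 3.78 ± 0.22 (13.7-fold, limma adjusted p = 1.31e-08), and Trem2, a receptor of lipid-handling macrophages, by 3.47 ± 0.10 (11.1-fold, adjusted p = 4.08e-12). Gpnmb rose by 2.93 ± 0.11, Ms4a7 by 2.50 ± 0.13 and the lysosomal protease gene Ctss by 1.55 ± 0.08. Of 29 measured genes of the monocyte and macrophage list, 26 rose and none fell over all genes (27 higher and 1 lower when adjusted over the list alone), with a median of 1.03 and a camera adjusted p of 4.08e-33. That call also held at an adjusted p = 0.00312 with an estimated correlation.

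Matrix genes rose as well. Of 35 genes for fibrillar collagens and matrix structure, 26 were higher (28 adjusted over the list alone), with a median of 0.83 and a camera adjusted p of 1.45e-15. That call was lost with an adjusted p = 0.111 with an estimated correlation. Col1a1 and Col3a1, which encode chains of the main fibrillar collagens, rose by 1.23 ± 0.16 and 1.00 ± 0.15, fibronectin (Fn1) by 1.49 ± 0.17 and elastin (Eln) by 2.06 ± 0.24. Among 28 matrix proteases and their inhibitors, 16 rose and 2 fell (18 and 3 adjusted over the list alone). Their median was 0.41, with a camera adjusted p of 5.86e-09 and an adjusted p = 0.118 with an estimated correlation. Mmp12, the elastase of macrophages, rose by 3.00 ± 0.25 (8.02-fold), the inhibitor Timp1 by 2.57 ± 0.34 and the collagen-degrading Ctsk by 2.03 ± 0.11. The smooth muscle actin gene Acta2, a myofibroblast marker, did not pass (0.09 ± 0.16, adjusted p = 0.781). The myofibroblast and smooth muscle list had 2 members higher and 2 lower of 16, both over all genes and adjusted over the list alone. Its median of 0.09 and its test, which leaned down, differed in sign (camera adjusted p = 0.982).

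Genes of the DNA damage response and of dividing cells rose together. In the p53 list 14 of 27 genes rose and none fell (15 higher and 1 lower adjusted over the list alone; median 0.46, camera adjusted p = 2.27e-10, and adjusted p = 0.00312 with an estimated correlation). Gdf15, a stress-induced cytokine, rose by 2.86 ± 0.12 (7.28-fold), Psrc1 by 2.54 ± 0.13, the cell cycle inhibitor Cdkn1a by 1.89 ± 0.22 and Ccng1 by 1.37 ± 0.10. In the cell cycle list 35 of 41 genes rose (37 adjusted over the list alone), with a median of 1.36 and a camera adjusted p of 2.44e-20. That call had an adjusted p = 0.234 with an estimated correlation. The mitotic kinase Plk1 rose by 1.78 ± 0.24, Prc1 by 1.95 ± 0.30 and the thymidine kinase Tk1 by 1.45 ± 0.20. Transcripts of thymocytes were high on 2 of these 5 arrays: Rag1 read 10.03 and 10.88 on replicates 1 and 4 of bleomycin with LNA-control, against 5.43 to 6.10 on the 14 other arrays. Without those arrays the cell cycle median was 1.05 and 27 members rose.

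Epithelial genes of injury rose while endothelial and some leukocyte genes fell. Of 18 genes of transitional and injured epithelium 13 rose (14 adjusted over the list alone; median 0.80, camera adjusted p = 7e-10, and adjusted p = 0.0153 with an estimated correlation), among them Cldn4 by 1.62 ± 0.20, Krt8 by 0.81 ± 0.10 and Clu by 0.83 ± 0.09. Of 27 endothelial genes 17 fell (19 lower and 1 higher adjusted over the list alone; median -0.42, camera adjusted p = 2.08e-10, and adjusted p = 0.0824 with an estimated correlation). The growth factor receptor Kdr changed by -0.95 ± 0.10 and the angiopoietin receptor Tek by -0.73 ± 0.11. Among 14 genes of natural killer and cytotoxic cells 9 fell (12 adjusted over the list alone; median -0.51, camera adjusted p = 3.43e-07, and adjusted p = 0.136 with an estimated correlation), including Gzma at -0.97 ± 0.14. Of 17 neutrophil genes 9 fell and 3 rose (10 and 4 adjusted over the list alone; median -0.65, camera adjusted p = 0.00107, and adjusted p = 0.0337 with an estimated correlation). S100a8 and S100a9, abundant in neutrophils, changed by -1.23 ± 0.11 and -1.14 ± 0.11, whereas Lcn2, which epithelium also makes, rose by 1.99 ± 0.20. Alveolar macrophage genes went both ways, 4 of 15 higher and 4 lower (5 and 4 adjusted over the list alone), with Ctsk at 2.03 ± 0.11, Fabp1 at -2.91 ± 0.19 and Krt79 at -1.33 ± 0.11.

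The other lists that shifted with bleomycin and LNA-control had medians between -0.32 and 0.46, and their calls were lost with an estimated correlation. Higher were dendritic cells (median 0.46, adjusted p = 0.157 with an estimated correlation), chemokines and cytokines (0.33, 0.301), T cells (0.32, 0.564), collagen processing and crosslinking (0.21, 0.296), the TGF-beta pathway (0.21, 0.296) and the interferon response (0.21, 0.564), each pair giving the median and that p. Lower were B cells and plasma cells (-0.32, 0.432), ciliated epithelium (-0.25, 0.296) and eosinophils and mast cells (-0.20, 0.296). Over all genes the members higher and lower were 9 and 1 of 15 for dendritic cells (11 and 1 adjusted over the list alone), 15 and 3 of 42 for chemokines (17 and 3), 3 and 0 of 19 for T cells (3 and 0), 7 and 2 of 22 for collagen processing (11 and 2), 10 and 3 of 28 for the TGF-beta pathway (10 and 5), 7 and 1 of 28 for interferon (7 and 1), 1 and 5 of 16 for B cells (1 and 8), 0 and 4 of 21 for cilia (0 and 4) and 0 and 4 of 14 for eosinophils (0 and 4). The T cell list lost its preset call without any 1 of 4 arrays, the TGF-beta list without replicate 1 of PBS with LNA-control (adjusted p = 0.0697) and the interferon list without replicate 4 of bleomycin with LNA-control (0.0707). Without the arrays rich in thymus transcripts the T cell median was -0.14. The dendritic cell growth factor receptor Flt3 rose by 1.01 ± 0.14, the chemokine gene Ccl12 by 2.35 ± 0.23 and the interferon-induced Oas1a by 0.94 ± 0.14. Heart muscle genes were lower (median -0.23, camera adjusted p = 0.00947, 6 of 15 lower over all genes, 6 lower and 1 higher adjusted over the list alone, and adjusted p = 0.432 with an estimated correlation). Fat genes were higher as a set under the preset correlation (median 0.42, camera adjusted p = 0.0163, and adjusted p = 0.432 with an estimated correlation), while 0 of 12 passed by themselves in limma, both over all genes and adjusted over the list alone. Without replicate 3 of PBS with LNA-control the fat median was 0.24 and the call was lost (camera adjusted p = 0.166). The lists for resident lung fibroblasts, alveolar macrophages, type 2, type 1 and club epithelium, caveolae, NRF2 and unfolded protein responses, earlier miR-199a-5p targets, immediate early genes, the circadian clock, red blood cells, thymus and sex-linked genes did not pass, with medians between -0.31 and 0.61.

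In all, limma called 3651 genes at an adjusted p under 0.05, 2003 higher and 1648 lower, and 371 of them changed at least 2-fold. Over all genes, called or not, the arrays of the groups did not overlap for 5277 (25.3%), where chance gives 3.57%, and 3341 of these were among the called. The count rose to 6713 with array weights. It fell to 2293 without replicate 3 of PBS with LNA-control, to 2258 without the arrays rich in thymus transcripts and to 1681 with the fat and heart lists as covariates. With the replicate number as a block it was 2429.

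**Figure D1:**
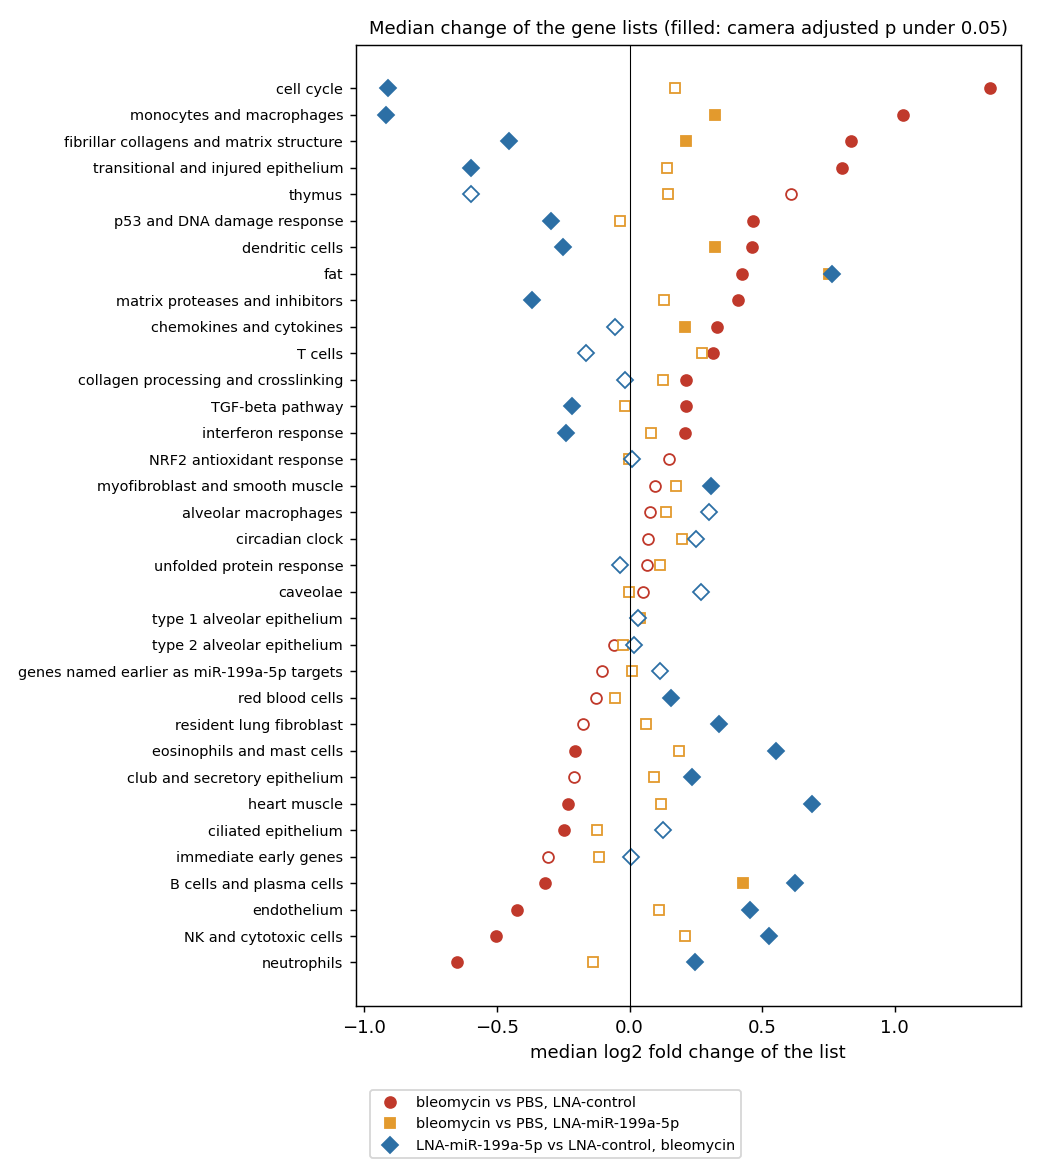
Median log2 fold change (x axis) of 34 gene lists (y axis) in 3 comparisons: bleomycin against PBS with LNA-control (circles) or LNA-miR-199a-5p (squares), and LNA-miR-199a-5p against LNA-control in bleomycin lungs (diamonds). Filled symbols passed camera at its preset correlation. The macrophage median was 1.03 with LNA-control and 0.32 with LNA-miR-199a-5p.

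The next comparison asked for the effect of bleomycin in lungs given LNA-miR-199a-5p. Here the acute-phase gene Saa3 rose most (2.85 ± 0.54, 7.19-fold, limma adjusted p = 0.00717), as far as with LNA-control (2.84 ± 0.54). Cxcl13, a chemokine that attracts B cells, rose by 1.87 ± 0.49. Some genes of B cells and plasma cells rose: the antibody joining chain Jchain by 1.85 ± 0.40, Cd79a by 1.14 ± 0.27 and Cd37 by 1.12 ± 0.19. Of 16 genes on that list 6 rose and 10 did not pass (9 higher adjusted over the list alone; median 0.43, camera adjusted p = 0.000237, but adjusted p = 0.61 with an estimated correlation). Macrophage genes rose less far: 13 of 29 were higher (17 adjusted over the list alone; median 0.32, camera adjusted p = 2.97e-07, and adjusted p = 0.61 with an estimated correlation), with Trem2 at 0.67 ± 0.10 and Gpnmb at 0.46 ± 0.11. Matrix genes had a median of 0.21, 5 higher and 1 lower of 35 (10 and 2 adjusted over the list alone; camera adjusted p = 0.0475, and adjusted p = 0.801 with an estimated correlation), a call that was lost without any 1 of 4 arrays.

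Dendritic cell genes (median 0.32, adjusted p = 0.61 with an estimated correlation), chemokines and cytokines (0.21, 0.741) and fat genes (0.75, 0.61) were the other lists that shifted under the preset correlation. Of 15 dendritic cell genes 6 rose and 1 fell (9 and 1 adjusted over the list alone) and of 42 chemokines and cytokines 8 rose (11). In the fat list 6 of 12 rose both over all genes and adjusted over the list alone, and Adipoq and Cfd, both made by fat cells, rose by 1.39 ± 0.32 and 1.30 ± 0.22. This rested on 1 array: without replicate 3 of PBS with LNA-miR-199a-5p the fat median was 0.22 (camera adjusted p = 0.0811) and Adipoq 0.83 (limma adjusted p = 0.0551), and both calls were lost, while Cfd kept its own. Cell cycle genes had a median of 0.17 (camera adjusted p = 0.132) and p53 genes -0.04 (camera adjusted p = 0.994). Tgfb1 rose by 0.86 ± 0.24, Acta2 by 0.55 ± 0.16 and the muscle filament gene Des by 0.74 ± 0.20, beside squamous epithelium transcripts that were near the bottom of the scale on 1 PBS array of this arm (Krt13 at 5.59 on replicate 3 against 11.38 to 15.73 on the other arrays). Without that array the calls of Cxcl13 (1.48, limma adjusted p = 0.0971), Jchain (1.55, 0.0507), Gpnmb (0.38, 0.067), Acta2 (0.47, 0.137) and Des (0.61, 0.102) were lost as well. Tgfb1 lost its call without replicate 1 or 2 of PBS with LNA-miR-199a-5p (0.78, 0.103 and 0.80, 0.096) or replicate 4 of bleomycin with it (0.78, 0.0657).

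Limma called 2786 genes in this arm, 1525 higher and 1261 lower, 100 of them at least 2-fold. The arrays did not overlap for 4315 of all genes (20.7%, where chance gives 3.57%), and 2440 of these were called. This count moved widely: it was 1360, 1400 and 1186 without replicates 1, 2 and 3 of PBS with LNA-miR-199a-5p, 1721 without replicate 5 of bleomycin with LNA-miR-199a-5p, 271 when only these 8 arrays entered the fit, 663 with the replicate number as a block and 6 with squamous epithelium, brown fat and heart lists as covariates.

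The interaction, which tests whether the effect of bleomycin differed between the LNA arms, passed for 1462 genes. The rise of macrophage genes was smaller with LNA-miR-199a-5p (interaction median -0.77, camera adjusted p = 1.13e-22, and adjusted p = 0.0149 with an estimated correlation; 19 of 29 lower, 22 adjusted over the list alone), and so was that of p53 genes (-0.38, camera adjusted p = 2.92e-10, and adjusted p = 0.00397 with an estimated correlation; 11 of 27 lower, and 12 lower and 1 higher adjusted over the list alone). The interaction was -3.80 for Spp1, -2.81 for Gdf15, -2.79 for Trem2, -1.24 for Fn1 and -0.98 for Col1a1, and 2.50 for Fabp1. Saa3 (0.01, adjusted p = 0.995) and Dnm1 (-0.14, adjusted p = 0.568) did not pass.

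Across the 3651 genes changed with LNA-control, the effects of bleomycin in the arms correlated with Pearson's r = 0.536 and Spearman's rho = 0.517 across genes, which are not independent replicates. Over all genes r was 0.365 and rho 0.336. Simulated unchanged groups gave an r of -0.854 to 0.699 over all genes and of -0.899 to 0.674 over the changed genes, so r by itself does not set the data apart from them. The covariance over all genes was 0.0377, where simulated unchanged groups gave -0.019 to 0.0176. No array is shared by these effects, but values of PBS arrays with the same replicate number moved together, which adds to the covariance. With PBS arrays of different replicate numbers in the arms the mean covariance was 0.0316 (0.0235 to 0.0403 in 6 splits), against -0.0304 to 0.0229 in simulated unchanged groups. Across the changed genes r was 0.501 with these splits and 0.461 with the replicate number as a block. Of the genes higher with LNA-control 369 were also higher in the other arm, where 146.4 would be shared by independent calls, and of the lower ones 317, against 99.61. The pairing of PBS arrays can add to these numbers. With PBS arrays of different replicate numbers in the arms, and fewer arrays, 0 to 90 higher genes were shared, more than independent calls give in 5 of 6 splits, and 2 to 39 lower genes, more in 6 of 6. The count of interaction genes was 632 to 2215 with single arrays left out, lowest without replicate 2 of PBS with LNA-control and highest without replicate 3 of bleomycin with LNA-control. It rose to 3862 with array weights. It was 947 with the replicate number as a block, 733 with RNA integrity as a covariate, 525 without the arrays rich in thymus transcripts, 513 without the PBS arrays that lacked brown fat transcripts, 184 with fat and heart covariates and 15 with squamous, brown fat and heart covariates.

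**Figure D2:**
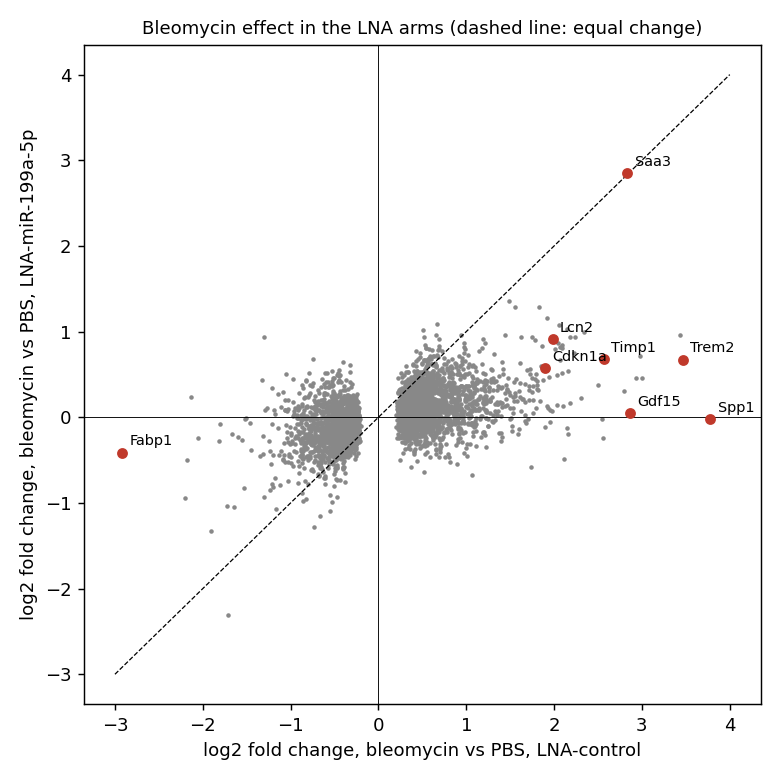
Log2 fold change after bleomycin with LNA-control (x axis) and with LNA-miR-199a-5p (y axis) for the genes that passed with LNA-control; the dashed line marks equal change. Saa3 lies on the line at 2.84 and 2.85, while Spp1 lies at 3.78 and -0.02.

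Within bleomycin lungs, LNA-miR-199a-5p against LNA-control asked what the inhibitor did to injured tissue. Most of the macrophage and matrix genes above were lower with the inhibitor. Spp1 changed by -3.49 ± 0.19 (11.3-fold lower, limma adjusted p = 9.56e-09), to a mean of 10.53 against 14.02 with LNA-control and 10.24 in PBS lungs with LNA-control. Trem2 changed by -2.31 ± 0.09, Gpnmb by -1.78 ± 0.09 and Mmp12 by -2.51 ± 0.21. Of 29 macrophage genes 25 fell (26 adjusted over the list alone; median -0.92, camera adjusted p = 7.01e-25, and adjusted p = 0.0104 with an estimated correlation). Of 35 matrix genes 24 fell and 1 rose (26 and 1 adjusted over the list alone; median -0.46, camera adjusted p = 4.87e-12, but adjusted p = 0.155 with an estimated correlation), with Col1a1 at -1.12 ± 0.14, Fn1 at -1.23 ± 0.15, Eln at -1.67 ± 0.21 and Timp1 at -1.76 ± 0.29.

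Genes of other injury responses were lower too. Of 27 p53 genes 16 fell and 1 rose (17 and 1 adjusted over the list alone; median -0.30, camera adjusted p = 2.76e-09, and adjusted p = 0.00666 with an estimated correlation), with Psrc1 at -2.08 ± 0.11, Gdf15 at -1.92 ± 0.11, Ccng1 at -1.28 ± 0.09 and Cdkn1a at -0.77 ± 0.19. Of 18 transitional epithelium genes 11 fell (12 adjusted over the list alone; median -0.60, camera adjusted p = 2.68e-07, and adjusted p = 0.0425 with an estimated correlation), with Lgals3 at -0.63 ± 0.08 and Krt18 at -0.62 ± 0.08. Of 41 cell cycle genes 32 fell (36 adjusted over the list alone; median -0.91, camera adjusted p = 1.92e-15, and adjusted p = 0.242 with an estimated correlation), beside the thymus transcripts on 2 LNA-control arrays. Proteases and inhibitors (median -0.37, adjusted p = 0.155 with an estimated correlation), the TGF-beta pathway (-0.22, 0.242), dendritic cells (-0.25, 0.453) and interferon genes (-0.24, 0.491) were lower under the preset correlation. Over all genes the members higher and lower were 1 and 15 of 28 proteases and inhibitors (3 and 18 adjusted over the list alone), 6 and 14 of 28 in the TGF-beta pathway (7 and 14), 1 and 7 of 15 for dendritic cells (2 and 7) and 3 and 10 of 28 for interferon (3 and 10). The dendritic cell list lost its call without any 1 of 4 arrays. Tgfb2 changed by -0.70 ± 0.08, while Tgfb1 did not pass (0.40 ± 0.21, adjusted p = 0.182). The type 1 epithelium list did not pass and went both ways, 7 of 20 higher and 6 lower, also when adjusted over the list alone. Its median of 0.03 and its test, which leaned down, differed in sign (camera adjusted p = 0.465). Ndnf and Igfbp2 of that list changed by -1.87 ± 0.11 and -1.36 ± 0.08.

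Endothelial, natural killer, B cell and granulocyte genes were higher with the inhibitor. The T cell list did not pass (median -0.16, 1 of 19 higher and 1 lower, none adjusted over the list alone, camera adjusted p = 0.224). Its mean was 9.249 and 9.688 on replicates 1 and 4 of bleomycin with LNA-control, the arrays rich in thymus transcripts. On replicates 2, 3 and 5 it was 8.531, 8.607 and 8.721, against 8.614 to 8.967 with the inhibitor. The sign of the T cell median may therefore rest on the thymus transcripts. Of 27 endothelial genes 20 rose (21 adjusted over the list alone; median 0.45, camera adjusted p = 6.41e-09, and adjusted p = 0.109 with an estimated correlation), with Plvap, a marker of vessel fenestrae, at 0.98 ± 0.14, Tek at 0.60 ± 0.10 and Kdr at 0.47 ± 0.09. Of 17 neutrophil genes 7 rose and 2 fell (8 and 2 adjusted over the list alone; median 0.25, camera adjusted p = 0.00129, and adjusted p = 0.0425 with an estimated correlation), with S100a9 at 1.10 ± 0.09 and S100a8 at 1.01 ± 0.10. Natural killer and cytotoxic genes (median 0.53, adjusted p = 0.155 with an estimated correlation), B cell genes (0.62, 0.242) and eosinophil and mast cell genes (0.55, 0.0866) were higher under the preset correlation. Their members higher and lower were 12 and 1 of 14 (the same adjusted over the list alone), 10 and 0 of 16 (11 and 0) and 9 and 0 of 14 (9 and 0), among them Gzma at 0.78 ± 0.12, Ncr1 at 0.63 ± 0.09, Cd79b at 0.96 ± 0.15, Prg2 at 1.26 ± 0.15 and Il5ra at 0.66 ± 0.10. Fabp1 rose by 2.35 ± 0.16, Krt79 by 1.63 ± 0.10 and the growth factor binding protein gene Igfbp3 by 1.67 ± 0.20.

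Transcripts of heart muscle and fat differed between the same bleomycin groups. Whether they came from within the lung or from tissue around it was not tested. Heart muscle genes rose by a median of 0.69 (12 of 15, 14 adjusted over the list alone; camera adjusted p = 2.68e-07, and adjusted p = 0.155 with an estimated correlation), with the atrial Myl7 at 0.87 ± 0.14 and Tnni3 at 0.89 ± 0.12. The heart list had a mean of 11.11 with the inhibitor against 10.46 with LNA-control. Fat genes rose by 0.76 (6 of 12, 7 adjusted over the list alone; camera adjusted p = 0.00101, and adjusted p = 0.329 with an estimated correlation). Resident lung fibroblasts (median 0.34, adjusted p = 0.242 with an estimated correlation), myofibroblasts and smooth muscle (0.31, 0.186), club epithelium (0.24, 0.329) and red blood cells (0.16, 0.242) were also higher under the preset correlation. Their members higher and lower were 9 and 1 of 20 (10 and 2 adjusted over the list alone), 10 and 1 of 16 (11 and 1), 5 and 2 of 16 (7 and 2) and 4 and 0 of 11 (4 and 0), with Acta2 at 0.61 ± 0.14 and Des at 0.81 ± 0.17. The club list lost its call without any 1 of 7 arrays and the resident fibroblast list without replicate 5 of bleomycin with LNA-miR-199a-5p (adjusted p = 0.0529). With squamous epithelium, brown fat and heart lists as covariates the resident fibroblast median turned slightly negative.

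Limma called 5188 genes here, 2803 higher and 2385 lower, and 248 of them at least 2-fold. Over all genes, called or not, the arrays of the groups did not overlap for 2871 (13.8%), where chance gives 0.794%, and 2682 of these were called. The count was 2981 with RNA integrity as a covariate and 2356 without the arrays rich in thymus transcripts. With the fat and heart lists as covariates 153 genes passed, and with squamous epithelium, brown fat and heart lists 81. In the former fit Spp1 (-2.78, adjusted p = 0.000719), Trem2 (-2.46, 1.3e-05), Gdf15 (-1.81, 0.000816), Mmp12 (-1.40, 0.033) and Fabp1 (1.70, 0.00137) still passed in limma, each pair giving the log2 fold change and adjusted p. Timp1 (-0.14, adjusted p = 0.924) and Acta2 (-0.01, 0.994) lost nearly all of their change. The endothelial genes Kdr (0.16, limma adjusted p = 0.748) and Tek (0.28, 0.543) lost the larger part of theirs. So did Col3a1 (-0.40, 0.535), Ccl12 (-0.23, 0.813), Oas1a (-0.26, 0.62) and Prc1 (-0.44, 0.674), among others. Col1a1 (-0.83, adjusted p = 0.203), Fn1 (-0.88, 0.189), Eln (-1.43, 0.164), Plvap (0.61, 0.352) and Igfbp3 (1.32, 0.152) kept the larger part of theirs and Cdkn1a (-1.12, 0.218) all of it, but with standard errors of 0.25 to 0.42 they did not pass. The cell cycle median was -0.03 with fat and heart covariates and 0.25 with squamous, brown fat and heart covariates, and the interferon median was 0.13 and 0.27. Within bleomycin with LNA-control the heart list itself ran against Timp1. In replicate order the heart list read 10.33, 10.54, 10.73, 10.38 and 10.3, and Timp1 12.92, 12.16, 11.37, 12.81 and 13.1. A heart covariate can therefore also take away part of the injury response, so a lost call does not by itself point to other tissue.

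Across the 3651 genes changed by bleomycin with LNA-control, the effect of bleomycin and that of the inhibitor had r = -0.865 and rho = -0.844 across genes. Over all genes r was -0.514 and rho -0.415. Both effects contain the same 5 bleomycin arrays with LNA-control, which brings a negative value by itself: simulated unchanged groups had a mean r of -0.392 over all genes (-0.852 to 0.391), which contains the r of the data. Their mean covariance was -0.00922 (-0.03 to 0.00393), against -0.0555 in the data. With those arrays split so that no array entered both effects, the mean r over all genes was -0.416 (-0.515 to -0.227) and the mean covariance -0.0475 (-0.0577 to -0.0271). When the changed genes were also chosen from 1 part of the split alone, their mean r with the effect from the other part was -0.806 (-0.871 to -0.674 in 20 splits). Of the 2003 genes higher after bleomycin 1158 were lower with the inhibitor and 20 higher, and of the 1648 lower ones 913 were higher and 28 lower.

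**Figure D3:**
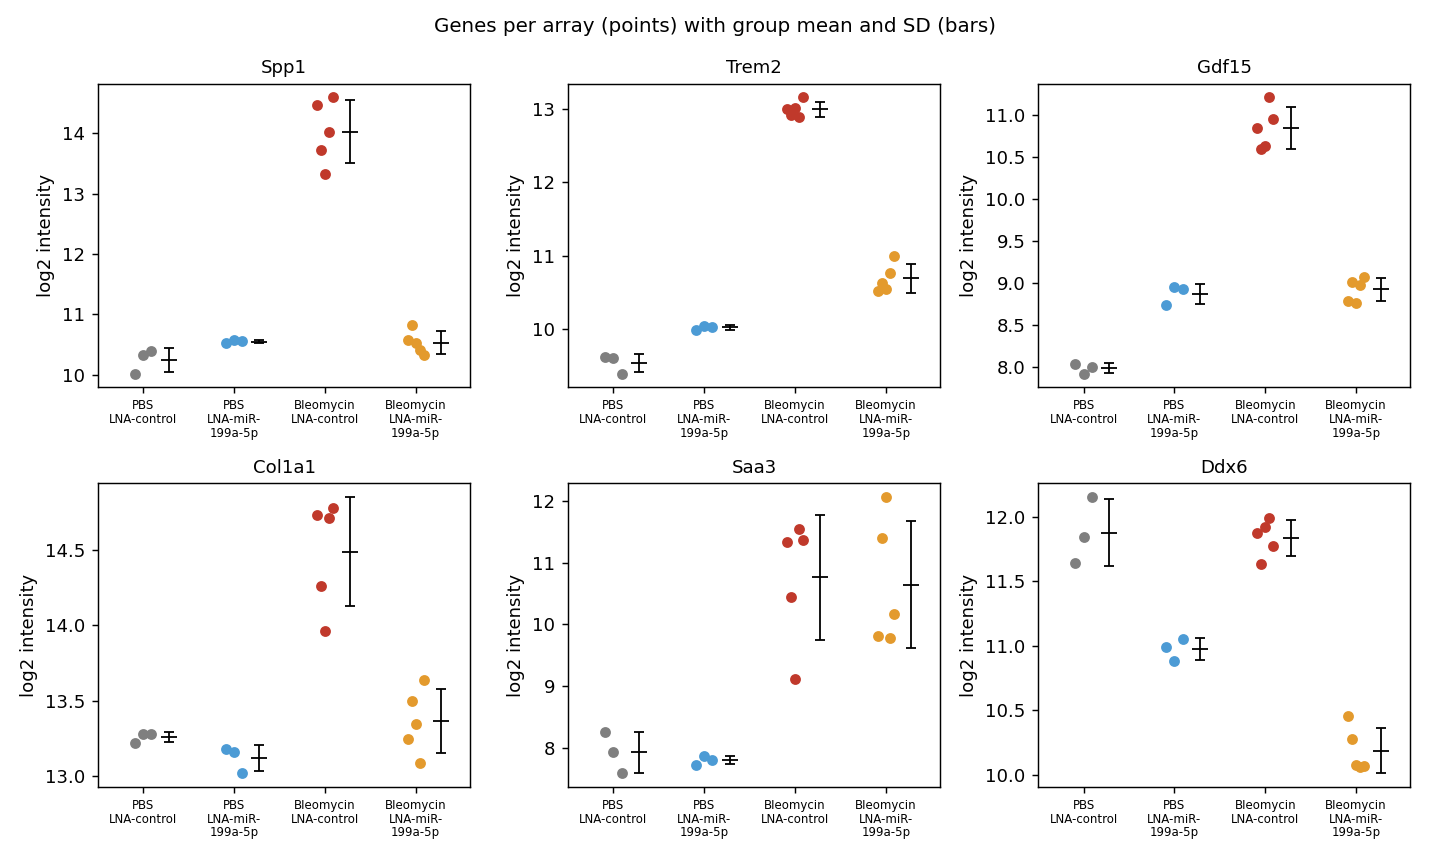
Log2 intensity (y axis) of 6 genes on each array (points) in the 4 groups (x axis), with group means and standard deviations (bars). Spp1 had a mean of 14.02 with bleomycin and LNA-control and 10.53 with bleomycin and LNA-miR-199a-5p, while Ddx6 was lower in both groups given LNA-miR-199a-5p.

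**Figure D4:**
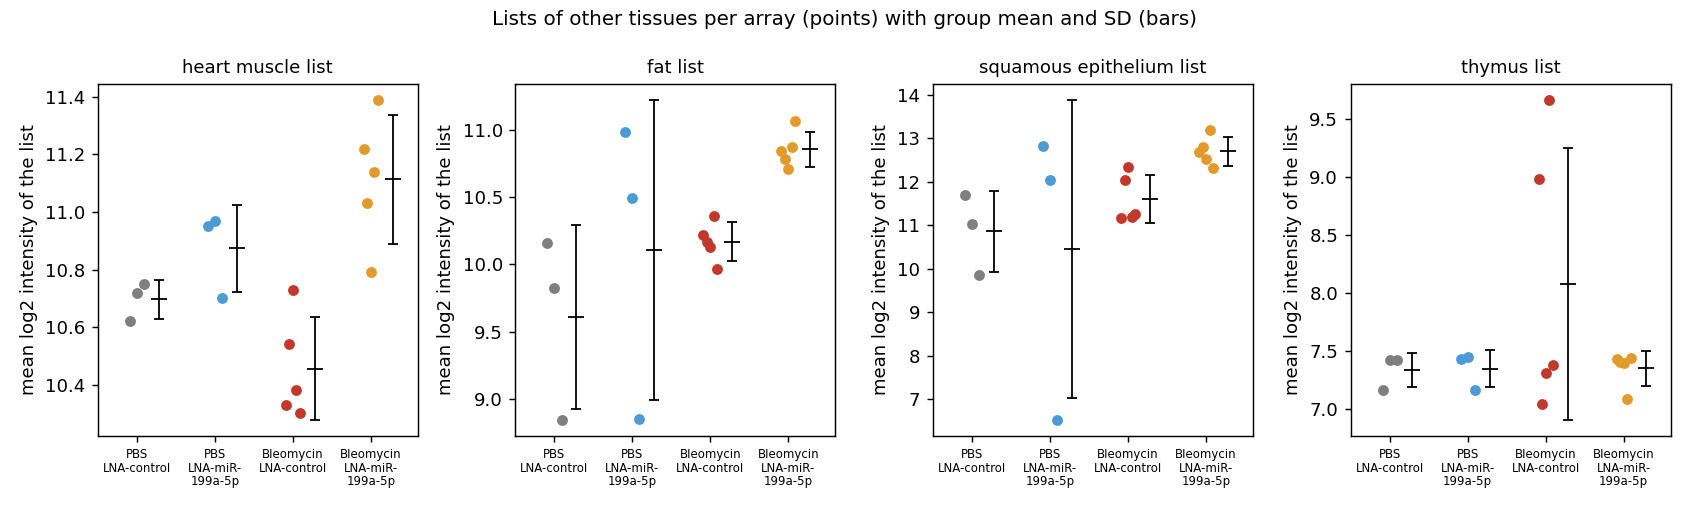
Mean log2 intensity (y axis) of the heart muscle, fat, squamous epithelium and thymus lists on each array (points) in the 4 groups (x axis), with group means and standard deviations (bars). The thymus list stood high on 2 arrays of bleomycin with LNA-control, and the heart muscle list had means of 10.46 and 11.11 in the bleomycin groups.

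In PBS lungs limma called 10 genes for the inhibitor, a count that moved from 0 to 394 between alternatives. Ddx6, which encodes an RNA helicase of mRNA decay and microRNA repression, changed by -0.90 ± 0.13 (limma adjusted p = 0.0289), the transporter gene Atp13a3 by -0.85 ± 0.14 (adjusted p = 0.0368) and Cyyr1 by -1.28 ± 0.15 (adjusted p = 0.00356). All 3 were lower with the inhibitor in bleomycin lungs as well, by -1.65 ± 0.10, -1.20 ± 0.11 and -1.15 ± 0.12. In PBS lungs Ddx6 lost its call without any 1 of 5 arrays and Atp13a3 without any 1 of 9, while Cyyr1 kept it without each of the 16. The genes that rose were Cxcr1 (1.21), Il22ra2 (1.08), the neutrophil granule gene Camp (0.89 ± 0.14), Gdf15 (0.89 ± 0.14), Rhd (0.76), the alarmin Il33 (0.69 ± 0.11) and Kel (0.60). Il22ra2 lost its call without any 1 of 13 of the 16 arrays. Rhd and Il33 lost theirs without any 1 of 9, Gdf15 without any 1 of 6, and Camp and Kel without any 1 of 5. Cxcr1, Il22ra2, Rhd and Kel fell outside the rule for naming genes and were chosen after their values were seen. Camp, Il22ra2, Rhd and Kel were also higher with the inhibitor in bleomycin lungs, where Gdf15 was lower. Over all genes the effects of the inhibitor in PBS and bleomycin lungs had r = 0.018 and rho = -0.0195, and their covariance of 0.00103 lay within the -0.0162 to 0.0183 of simulated unchanged groups.

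Limma called these 10 genes, 7 higher and 3 lower, and 1526 genes had an unadjusted p under 0.05. With array weights 394 genes passed, all 10 among them, and without the arrays poor in brown fat transcripts 31, with 7 of the 10. Values of PBS arrays with the same replicate number moved together, so the count with the replicate number as a block is given beside it: 3 genes over all arrays, and 2 genes, none of them among the 10, with PBS arrays alone (limma). With only the PBS arrays and no block 0 genes passed in limma. Without replicates 1, 2 and 3 of PBS with LNA-miR-199a-5p 3, 2 and 121 genes passed, without replicates 2 and 3 of PBS with LNA-control 2 and 4, without replicate 1 of bleomycin with LNA-control 6, and without replicate 2 of bleomycin with LNA-miR-199a-5p 2. In simulated data of this design 91.0% of changes of 1 on the log2 scale and 47.8% of changes of 0.5 were recovered. The simulated set had independent noise and 162 genes called, where the data had 10. More changed genes make the adjusted threshold looser, so these shares may overstate what could be found in PBS lungs. The lists for natural killer and cytotoxic cells (median -0.17, adjusted p = 0.724 with an estimated correlation) and B cells (-0.19, 0.954) were lower and the p53 list higher (0.13, 0.626) with camera at its preset correlation (adjusted p of 0.00109, 0.00238 and 0.013). Of their 14, 16 and 27 members 0, 0 and 1 passed over all genes, and adjusted over the list alone 1 natural killer gene fell, no B cell gene passed and 4 p53 genes rose. The p53 call was lost without replicate 2 of PBS with LNA-miR-199a-5p (adjusted p = 0.0538).

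Caveolin-1, reported earlier as a target of miR-199a-5p, was among the genes fixed beforehand. Cav1 changed by -0.58 ± 0.10 after bleomycin with LNA-control (limma adjusted p = 0.000923). With LNA-miR-199a-5p the effect of bleomycin was -0.11 ± 0.10 (adjusted p = 0.53), and the interaction was 0.48 (adjusted p = 0.0623). In bleomycin lungs it was 0.25 ± 0.09 with the inhibitor and passed narrowly (adjusted p = 0.04996). That call was lost without any 1 of 12 of the 16 arrays, and with the fat and heart covariates (0.24, adjusted p = 0.632). Of 19 measured genes on the list of earlier targets 5 were higher with the inhibitor in bleomycin lungs and 3 lower (7 and 3 adjusted over the list alone; median 0.12, camera adjusted p = 0.366), with Ets2 at 0.52 ± 0.07, Fzd4 at 0.37 ± 0.09 and Gsk3b at -0.54 ± 0.09. In PBS lungs the list had a median of -0.07 (camera adjusted p = 0.396). Dnm1 rose after bleomycin in both arms, by 0.61 ± 0.09 and 0.47 ± 0.09. Dnm3os, the transcript that carries miR-199a-2, was dim, with group means of 6.13 to 6.38, and passed in no comparison. Sftpc lay at the top of the scale on nearly every array, with a group mean of 18.32 in PBS lungs, so a change in it could not be read.

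In a principal component analysis of the 2000 genes with the largest variance, the first component held 40.0% of the variance and the second 29.3%. The second parted the bleomycin arrays with LNA-control, at 6.52 to 29.02, from all other groups, at -13.67 to -2.01. On the first, replicate 3 of PBS with LNA-miR-199a-5p, the array without squamous transcripts, lay lowest at -47.96. Its largest loadings were those of squamous genes such as Krt13, Lce3a and Lor, with the skeletal muscle gene Tnnc2 and the brown fat gene Ucp1 close behind. The first component also parted the bleomycin groups, at -6.86 to 7.00 with LNA-control and 14.09 to 23.69 with LNA-miR-199a-5p. The comparison of these groups thus lies partly along transcripts of other tissues.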

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

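The tests of heart and fat tissue, of RNA integrity, of thymus arrays, of the separation of inhibitor arrays and of genes chosen from 1 part of the LNA-control arrays were chosen after the data had been seen, while the counts under other splits of the arrays and the scaled response were fixed beforehand.

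The effect of bleomycin differed between the LNA arms for 1462 genes by the interaction test. Of the gene lists, 12 differed with camera at its preset correlation. The effect was smaller or more negative with LNA-miR-199a-5p for matrix structure (median -0.546), proteases and inhibitors (-0.378), monocytes and macrophages (-0.771), transitional epithelium (-0.490), the cell cycle (-1.07) and the p53 response (-0.378). It was larger or less negative for neutrophils (0.333), natural killer and cytotoxic cells (0.746), B cells and plasma cells (0.860), eosinophils and mast cells (0.525), endothelium (0.488) and heart muscle (0.501). The cell cycle value stands beside high thymus transcripts on some arrays of bleomycin with LNA-control. Squamous epithelium, brown fat and heart lists as covariates turned the cell cycle median positive. Without replicate 3 of PBS with LNA-miR-199a-5p the neutrophil call was lost (median 0.230, adjusted p = 0.104). With an estimated correlation the macrophage and p53 lists alone kept an adjusted p under 0.05.

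For bleomycin in both arms and for the inhibitor in bleomycin lungs, no other split tested called as many genes as the real one. This makes chance unlikely for these counts if the replicates are separate animals, which the labels do not state. For bleomycin with LNA-control 1 of 56 splits, the real one, gave 3651 genes, and the highest other gave 2149. With LNA-miR-199a-5p 1 of 56 gave 2786 genes, against 2428. For the inhibitor in bleomycin lungs 1 of 100 gave 5188, against 2554. For the interaction 1 of 100 reassignments of the LNA labels within treatments gave 1462, against 0. Those reassignments put the inhibitor effect in bleomycin lungs into the spread, so they stand for no LNA effect at all. They cannot test the interaction by itself. How many of them parted all PBS arrays of the same replicate number was not counted. In PBS lungs 10 splits are too few for a share under 0.05: 2 of them, the real one included, gave at least the 10 real genes, and the highest other gave 238, which points to a structure among those arrays. Of the 4 splits that part all arrays of the same replicate number, as the real one does, the highest other gave 0.

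Of the 2003 genes that rose after bleomycin with LNA-control 1158 were lower with the inhibitor, while the interaction test over all genes went both ways (641 higher, 821 lower). With the LNA-control arrays split, genes higher after bleomycin in 1 part had a mean median inhibitor effect of -0.347 against the other part (-0.507 to -0.151 in 20 splits). The explanations were weighed on the 1158 genes called higher after bleomycin with LNA-control and lower with the inhibitor, whose median of -0.527 follows from that choice and serves only as the value to compare with. Dilution of lung RNA by heart and fat RNA needs a fall of lung epithelial genes, and 74 of these had a median of 0.126. Its standard error of 0.0744 takes the genes as independent. Club and ciliated genes among them had medians of -0.21 and -0.249 after bleomycin with LNA-control, so a weaker response could mask a fall. The type 2 and type 1 lists, at -0.0582 and 0.0308 after bleomycin, had medians of 0.0182 and 0.0328 with the inhibitor. That argues against dilution as the whole source of the pattern. RNA integrity as a covariate left the median at -0.508 with 919 genes still called, so it does not account for the whole pattern. From the same response scaled by 1 factor of 0.269, 344 of 3651 genes departed, so 1 factor does not describe all of them. The factor was fitted to the same genes and then taken as known. Departures that go with tissue differences between arrays were not set apart. A difference in heart and fat tissue between the bleomycin groups cannot be told apart from an effect of the inhibitor: with those lists as covariates the median was -0.291, 1042 of the genes were still lower and 77 still called. The change shrank and the median standard error grew from 0.0994 to 0.181, and how much each took from the calls was not separated. Each list parts the groups on all 10 arrays, which keeps this open. Across the bleomycin arrays with LNA-control the heart list also ran against Timp1 and the cell cycle list, so its covariate can take away injury response as well.

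Ddx6, Atp13a3 and Cyyr1 were lower in both groups given LNA-miR-199a-5p. With RNA integrity as a covariate they kept at least 91.6% of their change in bleomycin lungs, which argues against it as the cause there. In PBS lungs both groups had a mean RNA integrity number of 8.33, so the covariate could not move the change and tests nothing. With heart and fat lists as covariates these genes kept at least 99.4% of their change in bleomycin lungs. That argues against heart and fat tissue there, as far as lists that part these groups can. The change in PBS lungs was not weighed in this way, and that fit kept 5 of the 10 calls there. A shared effect of the oligonucleotide on more genes could not be settled. The 8 inhibitor arrays were separated from the 8 control arrays by 115 genes, of which 5 passed in PBS lungs. With the bleomycin arrays as labelled, 1 of the 20 assignments of the PBS arrays, the real one, gave as many, and 20 are too few for a share under 0.05. The assignment with the PBS labels swapped gave 97, so the count says little about a common direction in PBS lungs. Over all genes the effects of the inhibitor in PBS and bleomycin lungs had r = 0.018, where simulated unchanged groups gave -0.517 to 0.645, so this r decides nothing. Whether the change in Ddx6, Atp13a3 and Cyyr1 acts through miR-199a-5p or through other pairing of the oligonucleotide was not tested.

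Cell cycle genes were higher after bleomycin with LNA-control, beside high thymus transcripts on 2 of the 5 arrays. Without these arrays the list median went from 1.36 to 1.05, with 27 of 41 members called one by one in limma in place of 35. The list mean on replicates 2, 3 and 5 of bleomycin with LNA-control was 9.13, 8.70 and 9.77, against 8.17 to 8.43 with PBS and LNA-control. Camera gave an adjusted p = 2.18e-17 without the arrays at its preset correlation, but 0.281 with an estimated correlation of 0.695, as it gave 0.234 with all arrays, so the shift against other genes is not established. For the rise of the genes themselves, thymus RNA may account for part but not for the whole. Other sources of dividing cells were not tested.

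Single arrays stood apart in 4 of 94 group tests made on list means, where chance gives about 1 in 20. Replicate 5 of bleomycin with LNA-miR-199a-5p had a matrix mean of 11.02 against 10.91 to 10.94 on the other arrays of its group, a TGF-beta pathway mean of 11.17 against 11.09 to 11.11, and an eosinophil and mast cell mean of 8.053 against 7.714 to 7.803. Replicate 4 of that group had a thymus mean of 7.088 against 7.401 to 7.443.

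Spots with no gene name, which the comparisons did not use and which include control spots, also passed the threshold when every spot was tested: 1230 after bleomycin with LNA-control, 1498 with LNA-miR-199a-5p, 10 for the inhibitor in PBS lungs, 2885 in bleomycin lungs and 200 for the interaction.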

How the results depend on the processing

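The covariates made of tissue lists, the arrays left out for their thymus or brown fat transcripts, the block within PBS arrays, the choice of genes from 1 part of the split and the PBS arrays of different replicate numbers were chosen after the data had been seen, and the other settings beforehand. The 5 gene counts and the list counts stayed within 1.5 times of their values under repeated quantile normalization, centring on the 75th percentile, the dimmest 30% of genes left out, the mean of probes and the trended, robust variance, and the rescalings moved no fold change by more than 0.156. Below, counts are in the order bleomycin with LNA-control (3651), bleomycin with LNA-miR-199a-5p (2786), inhibitor in PBS lungs (10), inhibitor in bleomycin lungs (5188) and interaction (1462), where a value moved by more than 1.5 times.

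A threshold of at least 2-fold gave 371, 100, 3, 248 and 287, which follows from its construction. An adjusted p under 0.1 gave 4646, 20 and 2533 for bleomycin with LNA-miR-199a-5p, the inhibitor in PBS lungs and the interaction. Testing every spot, which counts spots and not genes, gave 6382, 5599, 23 and 10590 for all but the last. Array weights gave 6713, 394 and 3862 for bleomycin with LNA-control, the inhibitor in PBS lungs and the interaction, the groups compared alone gave 271 and 0 for bleomycin with LNA-miR-199a-5p and the inhibitor in PBS lungs, and RNA integrity gave 1162, 2981 and 733 for bleomycin with LNA-miR-199a-5p, the inhibitor in bleomycin lungs and the interaction. The replicate block gave 2429, 663, 3 and 947 for all but the inhibitor in bleomycin lungs, and within PBS arrays 2 for the inhibitor in PBS lungs. The fat list gave 801 and 3 for bleomycin with LNA-miR-199a-5p and the inhibitor in PBS lungs. Fat and heart lists gave 1681, 424, 153 and 184 for all but the inhibitor in PBS lungs, of which 132 of the 153 were among the 5188. Squamous, brown fat and heart lists gave 1578, 6, 3, 81 and 15, with 70 of the 81 shared. Leaving out the thymus arrays gave 2258, 3, 2356 and 525 for all but bleomycin with LNA-miR-199a-5p, and leaving out the arrays poor in brown fat 2268, 791, 31 and 513 for all but the inhibitor in bleomycin lungs. Apart from the thresholds and the spots the cause was not tested.

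With single arrays left out the counts ran from 2293 to 3984, 1186 to 3534, 2 to 121, 3785 to 5640 and 632 to 2215. By more than 1.5 times the first moved without replicate 3 of PBS with LNA-control (2293), and the second without replicates 1, 2 and 3 of PBS with LNA-miR-199a-5p (1360, 1400, 1186) and replicate 5 of bleomycin with it (1721). The third moved without replicates 2 and 3 of PBS with LNA-control (2, 4), replicates 1 to 3 of PBS with LNA-miR-199a-5p (3, 2, 121), replicate 1 of bleomycin with LNA-control (6) and replicate 2 of bleomycin with LNA-miR-199a-5p (2). The interaction moved without replicates 1, 2 and 3 of PBS with LNA-control (844, 632, 689), 1 and 2 of PBS with LNA-miR-199a-5p (818, 840) and 1, 3, 4 and 5 of bleomycin with LNA-control (913, 2215, 918, 912).

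The numbers of shifted lists were 20, 6, 3, 20 and 12. An estimated correlation, which widens the test for most lists, left 4, 0, 0, 4 and 2. Fry called 0 for the inhibitor in PBS lungs, where array weights gave 6, the groups alone 7, fat and heart lists 6, squamous, brown fat and heart lists 9 and the arrays poor in brown fat left out 11. With LNA-miR-199a-5p fat and heart lists gave 12 and the other tissue lists 13. With single arrays left out the numbers ran from 18 to 22, 5 to 10, 2 to 10, 18 to 22 and 11 to 17, with 10 for the second without replicate 1 of PBS with LNA-miR-199a-5p, and for the third 5 without replicate 3 of PBS with LNA-control and 10 without replicate 3 of PBS with LNA-miR-199a-5p. The correlation of the bleomycin effects kept its sign in all alternatives (0.484 to 0.557 with single arrays left out, 0.501 with PBS arrays of different replicate numbers), and so did that with the inhibitor effect (-0.887 to -0.842, and -0.806 with the genes chosen from 1 part of the split).

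Some directions reversed. After bleomycin with LNA-control the T cell median was -0.0246 with fat and heart lists, -0.161 with squamous, brown fat and heart lists and -0.139 without the thymus arrays, and the interferon median -0.00144 and 0.0265 with the tissue lists, the latter reversed in its test. For the inhibitor in bleomycin lungs fat and heart lists turned Acta2 to -0.00921 and the interferon median to 0.126 (adjusted p = 0.0154), and the heart list itself to 0.001 by construction. Squamous, brown fat and heart lists turned the resident fibroblast median to -0.0287, interferon to 0.269 (adjusted p = 3.79e-05) and the cell cycle to 0.249 (adjusted p = 0.00992), with the heart list at 0.00883 by construction. They turned the cell cycle interaction to 0.129 and the B cell median for the inhibitor in PBS lungs to 0.0657. The cause of these was not tested. Of 390 fold changes of named genes, 90 were no longer called and 8 became called with fat and heart lists, 134 and 1 with squamous, brown fat and heart lists, 29 and 2 without the thymus arrays and 17 and 1 with RNA integrity. Both rescalings left all 390 on their side of the threshold.

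Dim genes limit what arrays can show: Dnm3os lay near 6 in every group, and Sftpc at the top value. The planned test of miR-199a-5p seed sites, with its alternatives, was not run for want of transcript sequence.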

Other observations

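The lists of squamous epithelium, skeletal muscle, brown fat and pituitary genes and the genes named here were chosen after the data had been seen.

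The 55 genes higher on all 8 arrays with LNA-miR-199a-5p than on all 8 with LNA-control included granule genes of myeloid cells and the genes Rhd, Kel, Sptb and Cldn13 of red blood cells, beside genes of other kinds. These kinds were picked from the genes themselves and were not tested for their share among the 55. Mpo, the myeloperoxidase of neutrophil granules, read 8.17 to 9.33 with the inhibitor and 7.00 to 8.12 without it, and Ctsg 7.03 to 7.80 against 6.12 to 6.88. In bleomycin lungs Mpo was higher by 1.25 (limma adjusted p = 9.98e-06) and Ctsg by 1.11 (adjusted p = 2.09e-05). In PBS lungs their changes of 0.82 and 0.61 did not pass (adjusted p = 0.123 and 0.334). Among the 60 lower genes, the uridylyl transferase gene Tut4 read 8.78 to 10.16 with the inhibitor and 10.49 to 11.54 without it, and Hook3 11.20 to 12.17 against 12.19 to 12.76.

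Transcripts typical of other tissues varied between arrays, and their origin was not tested. Growth hormone (Gh) read 10.84 and 9.80, prolactin (Prl) 11.43 and 10.38 and the hormone subunit Cga 9.23 and 8.40 on replicates 1 and 2 of PBS with LNA-miR-199a-5p, and each was at most 5.60 on the other 14 arrays. Of 12 measured pituitary genes not looked at before, 6 were highest on those arrays: Fshb, Chga, Chgb, Scg2, Drd2 and Dlk1. Dntt, a gene of thymocytes, read 11.10 and 12.17 on replicates 1 and 4 of bleomycin with LNA-control and 6.56 to 7.35 elsewhere. Krt13 read 5.59 on replicate 3 of PBS with LNA-miR-199a-5p and 11.38 to 15.73 elsewhere. The brown fat gene Ucp1 read 5.57 and 5.56 on replicates 3 of the PBS groups and 7.65 to 13.86 elsewhere. Mean values of the squamous list were 10.86, 10.46, 11.59 and 12.70 in PBS with LNA-control, PBS with LNA-miR-199a-5p, bleomycin with LNA-control and bleomycin with LNA-miR-199a-5p, and of the skeletal muscle list 8.99, 8.99, 9.72 and 10.69.

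Il1b read 13.06 on replicate 1 of PBS with LNA-control and 9.25 to 10.60 on all other arrays. The proliferation gene Mki67 read 12.36, 11.43, 10.66, 12.48 and 12.20 on replicates 1 to 5 of bleomycin with LNA-control and 10.37 to 10.97 with bleomycin and LNA-miR-199a-5p.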
